A study of Mus musculus with 31 samples.

How the data were processed

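The series measured RNA from the hypothalamus of 4-month-old C57BL/6J mice, in 31 libraries that fall into 4 groups by maternal diet (control or obesogenic) and sex, as the labels give them. Per the labels' protocols, total RNA was isolated with the RNAqueous kit and libraries were made with Illumina TruSeq protocols. Per the submitters' processing notes, FastQC, TopHat2 2.0.13, Subread and edgeR were used with build mm10. Per the file headers, the deposited counts are whole numbers of read pairs per gene, made with featureCounts 1.6.2 on Ensembl GRCm38 release 94 genes, both ends mapped, a minimum mapping quality of 10, and the reverse strand. The command names neither multi-mapping nor multi-overlapping reads, which the tool then leaves out, so genes with near-identical copies (ribosomal protein genes with processed pseudogenes, mitochondrial genes with nuclear copies) and genes that overlap on 1 strand lose pairs, and their levels are uncertain. The counts were not normalized by the authors, 1 column per library, and 0 columns were left unused. The sequencing instrument, read length, batches, animals and litters are not given in the sources used here.

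Column names matched 31 library titles, and gene IDs were matched to symbols for 54409 of 54532 genes. Library totals of 23118626 to 38547288 pairs make 1 read worth 0.0259 to 0.0433 CPM. The closest pair of libraries differed by 7.67 times the sampling noise (chi-square per degree of freedom over genes), so 0 libraries were treated as repeats. Differences were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr with the 4 groups, which kept 18743 genes, TMM scaling, robust dispersions, and quasi-likelihood tests on 1 mean per group, so that all libraries shared 1 estimate of the spread per gene. The contrasts were diet in females, diet in males, their mean, their difference (the interaction), and females minus males within each maternal diet. p-values were adjusted with Benjamini and Hochberg's method over the genes tested in a contrast, with 0.05 as the threshold. Intervals are 95% intervals of the log2 fold change from the edgeR fit. Where a group had 0 reads, a fold is given as a bound against 3 counts over the group, which covers counting error only.

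Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 49 lists with at least 5 measured members; Y-linked genes, the last of 50 lists, were counted and not tested. The lists cover the respiratory complexes, mitochondrial genome and ribosome, cytosolic ribosome, citric acid cycle, glycolysis, fatty acid oxidation, lipid synthesis, mitochondrial biogenesis, antioxidant enzymes and nutrient sensing. They also cover feeding-stimulating and feeding-suppressing genes, leptin and insulin signalling, other neuropeptides, hypothalamic identity, sex steroid, thyroid and clock genes, and immediate early, glucocorticoid, unfolded protein, heat shock, proteasome, inflammatory and interferon genes. Markers of microglia, astrocytes, oligodendrocytes, their precursors, endothelial, mural, fibroblast, ependymal, tanycyte, choroid plexus, pituitary, thalamic, telencephalic, midbrain and blood cells, synaptic and perineuronal genes and X-linked escape genes with Xist complete them. An olfactory bulb list of 15 genes was written after the libraries had been compared; of these, Slc17a7, Calb2 and Th also stand in the thalamus, telencephalon or midbrain lists. The groups, tests, gene lists, most alternatives and the rule for named genes were chosen before the data were examined.

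That rule took, per contrast, the 10 genes of smallest p in each direction past the threshold without predicted or unnamed models. Where fewer than 5 passed, it took the 5 named genes of smallest p as values that did not pass, with sex chromosome genes reported as lists in the sex contrasts. It also took the 4 members of smallest p of each called list, of which the text prints a part, and always Agrp, Npy, Pomc, Cartpt, Hcrt, Pmch, Lepr, Mc4r and Insr for diet within a sex. A few genes that it took are not reported here or compared between settings. The alternatives chosen beforehand were DESeq2 1.42.0, limma voom with sample quality weights, RLE size factors, no filter, a filter of 1 CPM in 7 libraries, 2 surrogate variables (svaseq in sva 3.50.0), only the 2 groups compared, and leaving out the 2 libraries with 2 numbers in the title. Whether those titles mark renumbered animals or pools is not given in the sources used here. Libraries whose median correlation lay over 3 median absolute deviations below the median were also left out. For lists they were the estimated correlation, fry, 2 surrogate variables and the same left-out libraries. Alternatives chosen after seeing the data left out the 2 libraries against their sex label, or these and the 3 that stood apart, or corrected each library for a smooth trend (splines with 4 degrees of freedom) in gene length and GC content, with and without the 5. The test of the slope on gene length, with diet permuted 100000 times within each sex, was chosen after seeing the data too. GC content came from the longest reference transcript of each gene (GENCODE M21), which covered 99.92% of genes.

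The procedure was tested on simulated data made from these libraries. For diet in females, with 100 genes changed per size, 27% of 1.5-fold and 62% of 2-fold changes were recovered at an adjusted p under 0.05 among 18743 genes with 6 unchanged genes called, and 50% and 72% without the 5 libraries, with 7. A shift of -0.2 put into complex I was recovered as -0.19 with 0 other lists called. That 0 does not give the rate of false list calls, since other splits of these libraries called a median of 15 lists for diet in females. Other splits of the libraries were drawn within strata, 99 beside the real one, the diet labels within each sex and the sex labels within each diet. Correlations across libraries used log2(CPM + 1), with exact permutation tests within groups and 100000 permutations over all libraries, all 2-sided.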

Results

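Hypothalamic gene expression was profiled in 31 libraries of total RNA from C57BL/6J mice, an inbred strain, whose dams ate a control diet or an obesogenic diet rich in fat and sugar during pregnancy and lactation. Offspring were weaned to chow at postnatal day 21, and all of them, those of control dams included, ate the obesogenic diet for 4 weeks from 3 months of age. They were studied at 4 months. Female offspring of control dams gave 8 libraries, male offspring of control dams 8, female offspring of obesogenic dams 7 and male offspring of obesogenic dams 8. The deposited table held counts of read pairs for 54532 genes. The total per library was 28019596 to 36923748 pairs in control females and 23118626 to 38547288 in control males. It was 24627042 to 34232678 in obesogenic females and 26128150 to 36283599 in obesogenic males. At that depth 18743 genes were tested. The labels name neither animals nor litters, so p-values measured the spread between these libraries, which littermates or technical repeats would make too small. Levels of groups are CPM scaled with TMM factors, given as mean ± SD. Levels of single libraries, of Xist and Y-linked genes and in figures are CPM of the library total without these factors. Log2 fold changes are given ± SE from edgeR. Group names refer to the diet of the dam.

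Sex-linked genes were read first, because sex is one of the labels compared. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), the RNA that silences 1 X chromosome in females, lay between 205 and 716 CPM in 14 of the 15 libraries labelled female. These 14 had 0 reads of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. In 15 of the 16 libraries labelled male the summed level of these 4 genes was 73.2 to 157 CPM and Xist reached at most 0.536 CPM. The library labelled control female 7 had the male pattern, with 139 CPM of the Y-linked genes and 0.312 CPM of Xist. The library labelled control male 7 had the female pattern, with 575 CPM of Xist and 0 CPM of the Y-linked genes. Both stayed in the groups their labels give.

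**Figure D1:**
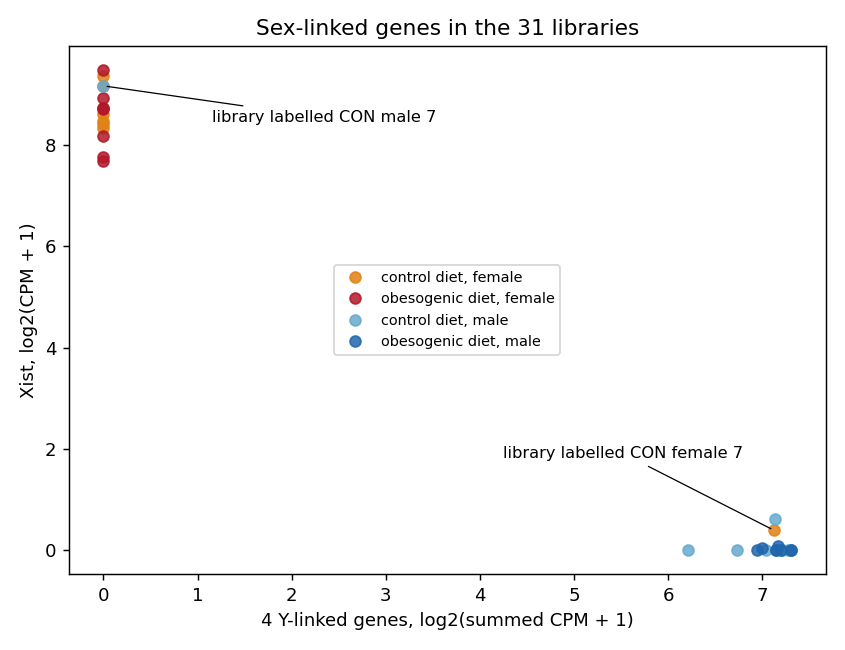
Each point is 1 of the 31 libraries; the horizontal axis gives the summed CPM of Ddx3y, Uty, Kdm5d and Eif2s3y and the vertical axis the CPM of Xist, both as log2(CPM + 1), with colour for maternal diet and labelled sex. The library labelled control female 7 (139 CPM Y-linked) sits among the males and the library labelled control male 7 (575 CPM Xist) among the females.

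3 other libraries stood apart from the rest by a preset rule on their correlations. Their median correlations with the remaining libraries were 0.910 for control female 5, 0.914 for control male 6 and 0.936 for obesogenic female 3, while the other 28 libraries ranged from 0.967 to 0.979. In control female 5 several hypothalamic peptide genes were nearly silent, though not Npy, at 118 CPM the highest of its group. Pmch, encoding melanin-concentrating hormone, stood at 0.0275 CPM and Hcrt, encoding the orexins, at 0.110 CPM, against 566 to 997 and 60.02 to 121 CPM in the 6 control female libraries not in doubt. Control male 6 and obesogenic female 3 had reads on 18734 and 18513 genes, against 21311 to 22918 in the 28 libraries that did not stand apart. Control male 6 also had the highest mean log2 CPM of the cytosolic ribosome and complex I genes of its group, and obesogenic female 3 the lowest of complex I in its group. Comparisons were also made without these 5 libraries, a choice made after the data were seen, which left 6 control females, 6 control males, 6 obesogenic females and 8 obesogenic males.

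**Figure D2:**
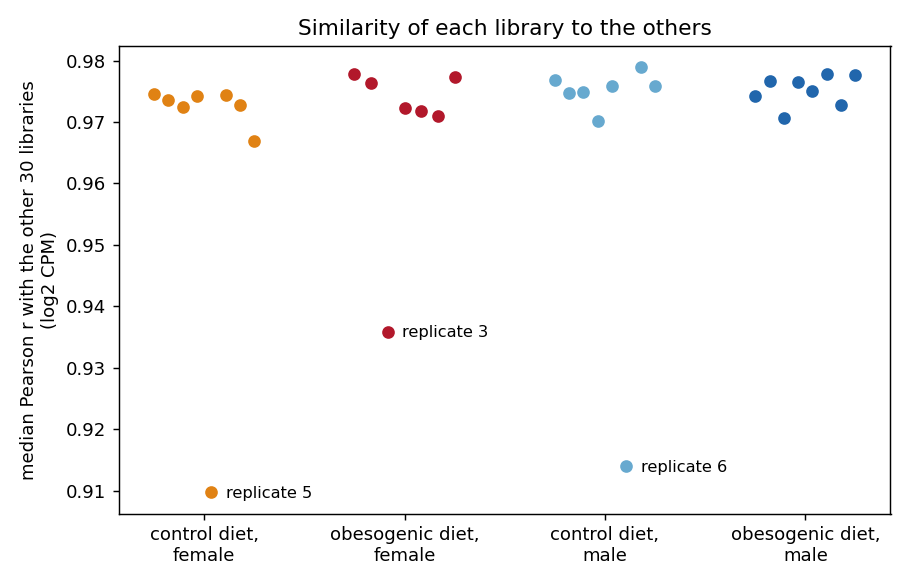
Each point is 1 library, placed by group on the horizontal axis, and the vertical axis gives its median Pearson correlation of log2 CPM with the other 30 libraries. Control female 5 (0.910), control male 6 (0.914) and obesogenic female 3 (0.936) lie below the other 28.

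To examine the effect of maternal diet in daughters, obesogenic females were compared with control females. Genes for the translation and respiration machinery fell together by the set test. Of the cytosolic ribosome, 76 of 77 measured protein genes were lower, with a median log2 fold change of -0.26 (camera adjusted p = 1.3e-14; adjusted p = 0.758 with an estimated correlation). The list mean was below the control female mean in 6 of 7 obesogenic female libraries. Of complex I, which feeds electrons from NADH into the respiratory chain, 34 of 36 genes were lower (median -0.20, adjusted p = 1.8e-07), with a lower list mean in 7 of 7 libraries. These calls, like those of the other lists called in this comparison, did not hold when the correlation between a list's genes was estimated. They had adjusted p = 0.758 with an estimated correlation for each of the 15 lists. Markers of hypothalamic neurons rose (21 of 22 higher, median 0.87, adjusted p = 9.1e-06; adjusted p = 0.758 with an estimated correlation). This median was 0.10 without the 5 libraries (adjusted p = 0.324).

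The other respiratory lists went the same way in females. All 13 cytochrome c oxidase genes (median -0.29, adjusted p = 2.5e-06), all 16 ATP synthase genes (median -0.24, adjusted p = 7.7e-06) and 11 of 13 genes of complexes II and III (median -0.22, adjusted p = 2.5e-04) were lower. These 3 lists had adjusted p = 0.758 with an estimated correlation. Mitochondrial ribosome genes (74 of 76 lower, median -0.12, adjusted p = 3.9e-07), the protein genes of the mitochondrial genome (12 of 13 lower, median -0.17, adjusted p = 0.0287) and proteasome genes (28 of 31 lower, median -0.11, adjusted p = 6.2e-04) fell too. All had adjusted p = 0.758 with an estimated correlation. Among single members, Ndufb9 of complex I had a log2 fold change of -0.38 ± 0.16 (58.9 ± 6.60 CPM in 8 control females and 45.1 ± 8.002 CPM in 7 obesogenic females). Cox8a of cytochrome c oxidase had -0.33 ± 0.13, Atp5g2 of ATP synthase -0.27 ± 0.10, Rpl15 of the ribosome -0.20 ± 0.081 and mt-Atp6 -1.38 ± 0.45. For all of these lists, 0 members passed in edgeR when adjusted over the list alone. With the 5 libraries left out the medians were -0.22 for the cytosolic ribosome, -0.14 for complex I, -0.19 for complex IV, -0.15 for ATP synthase and -0.13 for complexes II and III. All 5 were still past the threshold by camera, and none with an estimated correlation, where the smallest adjusted p was 0.511. After correction for gene length and GC content the mitochondrial genome's median turned to 0.093 (adjusted p = 0.852).

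Markers of meningeal fibroblasts (18 of 19 lower, median -0.35, adjusted p = 0.00553) and microglia (19 of 20 lower, median -0.19, adjusted p = 0.00771) fell in females. Both had adjusted p = 0.758 with an estimated correlation. Igfbp2, a fibroblast-list member that binds insulin-like growth factors, had a log2 fold change of -1.56 ± 0.49. Genes that suppress feeding (15 of 16 higher, median 0.57, adjusted p = 0.00680) and other neuropeptides (18 of 20 higher, median 0.29, adjusted p = 0.0130) rose. So did ependymal cilium genes (16 of 18 higher, median 0.35, adjusted p = 0.00660) and genes of the unfolded protein response (16 of 22 higher, median 0.090, adjusted p = 0.0324). These 4 lists had adjusted p = 0.758 with an estimated correlation. In the feeding-suppressing list 1 member passed when adjusted over the list alone, Cck, which encodes the satiety peptide cholecystokinin and went the other way (-1.59 ± 0.44). Its value was -0.35 ± 0.18 without the 5 libraries. Glp1r, the receptor for glucagon-like peptide 1, had 0.88 ± 0.37. Control female 5, in which Pmch and Hcrt were near silent, belonged to the control side of this comparison. None of these 6 lists passed without the 5 libraries. Their medians were 0.15 for feeding-suppressing genes, -0.047 for other neuropeptides, -0.076 for ependymal genes, 0.076 for the unfolded protein response, -0.21 for fibroblast and -0.087 for microglial markers. The adjusted p-values, in that order, were 0.344, 0.545, 0.478, 0.0624, 0.0912 and 0.206.

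The appetite genes named in advance did not pass in females. Npy (neuropeptide Y, which stimulates feeding; ENSMUSG00000029819, chromosome 6, 49822710 to 49829507) stood at 67.9 ± 26.2 CPM in 8 control females and 40.5 ± 24.5 CPM in 7 obesogenic females. Its log2 fold change was -0.75 ± 0.31 (edgeR adjusted p = 0.558), below the control mean in 5 of 7 libraries. Agrp (agouti-related peptide; ENSMUSG00000005705, chromosome 8, 105566698 to 105637393) had a log2 fold change of -0.34 ± 0.51, and Pomc (the melanocortin precursor; ENSMUSG00000020660, chromosome 12, 3954951 to 3960642) 0.33 ± 0.47. For Cartpt, another feeding-suppressing peptide gene, the value was 0.28 ± 0.28, for Hcrt 0.61 ± 0.58 and for Pmch 0.15 ± 0.57. The leptin receptor gene Lepr had 0.033 ± 0.19, the melanocortin receptor gene Mc4r 0.37 ± 0.37 and the insulin receptor gene Insr 0.052 ± 0.11. The 95% intervals ran from -0.35 to 0.42 for Lepr and from -0.18 to 0.28 for Insr, so changes inside them were not excluded. With the 5 libraries left out, none passed either, and several values moved. Agrp had -0.82 ± 0.33 (adjusted p = 0.553), below the control mean in 5 of 6 libraries, and Npy -0.72 ± 0.33. Pomc had 0.14 ± 0.38, Cartpt 0.18 ± 0.15, Hcrt 0.43 ± 0.43, Pmch 0.042 ± 0.20, Lepr 0.089 ± 0.18, Mc4r 0.20 ± 0.23 and Insr 0.0052 ± 0.088 in that set.

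In females edgeR called 0 of 18743 genes at an adjusted p under 0.05, the smallest being 0.5003, and 1522 genes had an unadjusted p under 0.05. DESeq2 called 6 genes and limma voom 0. Of the 6, Uty, Kdm5d, Eif2s3y and Ddx3y were Y-linked genes read, among libraries labelled female, only in control female 7. Gm45716 was lower and Mettl16 higher. Genes named here and in later comparisons because another tool called them were chosen after their values were seen. Mettl16, an RNA methyltransferase (ENSMUSG00000010554, chromosome 11, 74770830 to 74828525), also had the smallest p by edgeR. It stood at 50.2 ± 5.79 CPM in 8 control females and 64.8 ± 4.76 CPM in 7 obesogenic females. Its log2 fold change was 0.37 ± 0.082 (adjusted p = 0.5003), higher than the control mean in 7 of 7 libraries. The next 4 by p were Gabrd (-3.19 ± 0.73), Cpa6 (-5.69 ± 1.35), Doc2g (-4.69 ± 1.15) and Aqp1 (-5.02 ± 1.24). Their control levels spread widely, for instance 30.3 ± 82.2 CPM for Doc2g, and without the 5 libraries Doc2g had -0.0024 and Aqp1 -0.59 ± 0.65. In that set edgeR again called 0 genes, with 1571 at an unadjusted p under 0.05.

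**Figure D3:**
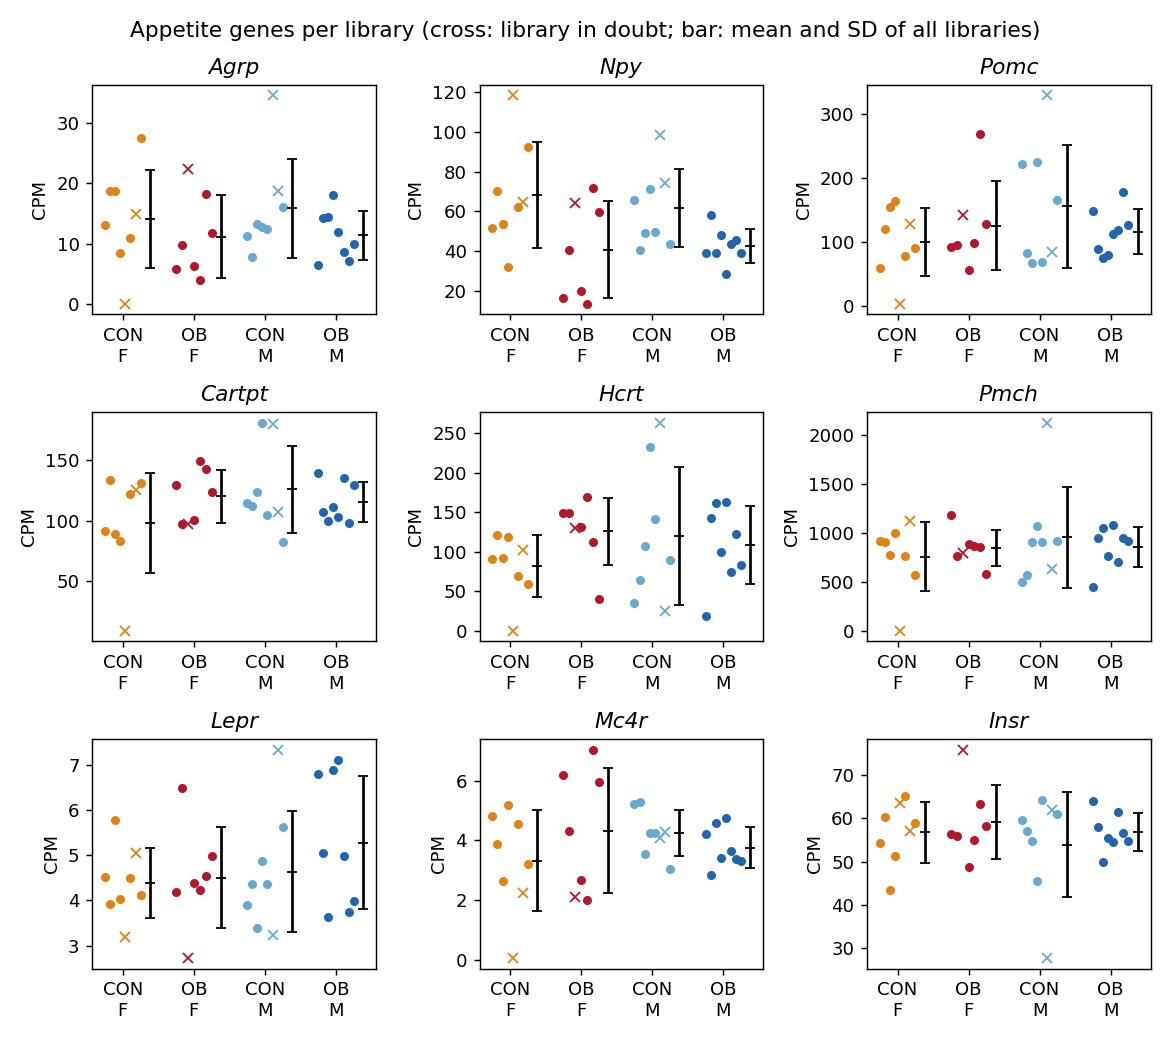
Each panel is 1 gene, the vertical axis gives CPM of the library total, points are single libraries, crosses are the 5 libraries in doubt, and bars beside the points show mean and SD of all libraries of a group (CON and OB, control and obesogenic dams; F and M, labelled females and males). Npy averaged 68.1 CPM in control and 40.7 CPM in obesogenic females, and 61.7 and 42.6 CPM in males, with overlapping points.

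In sons, the same comparison of obesogenic with control males again showed lower translation and respiration genes. Of the cytosolic ribosome, 76 of 77 protein genes were lower (median log2 fold change -0.25, camera adjusted p = 2.7e-22; adjusted p = 0.673 with an estimated correlation). The list mean was below the control male mean in 7 of 8 libraries, and in 5 of 8 without the 5 libraries. Complex I genes fell in the same way (35 of 36 lower, median -0.22, adjusted p = 7.2e-11; adjusted p = 0.673 with an estimated correlation), the list mean being lower in 8 of 8 libraries, and in 6 of 8 without the 5 libraries. Npy stood at 62.4 ± 22.2 CPM in 8 control males and 42.8 ± 8.50 CPM in 8 obesogenic males, below the control mean in 8 of 8 libraries. Its log2 fold change of -0.54 ± 0.29 did not pass (edgeR adjusted p = 0.940). It was -0.31 ± 0.31 without the 5 libraries, below the control mean in 7 of 8. The protein genes of the mitochondrial genome rose (11 of 13 higher, median 0.17, adjusted p = 0.0203; adjusted p = 0.673 with an estimated correlation). Their median without the 5 libraries was 0.14 (adjusted p = 0.0510).

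The remaining respiratory lists fell as well. Cytochrome c oxidase (13 of 13 lower, median -0.18, adjusted p = 4.3e-05) and ATP synthase (15 of 16, median -0.17, adjusted p = 5.8e-05) were called. So were complexes II and III (11 of 13, median -0.078, adjusted p = 0.0203) and the mitochondrial ribosome (72 of 76, median -0.11, adjusted p = 1.4e-10). Each of these 4 had adjusted p = 0.673 with an estimated correlation. Proteasome genes (29 of 31 lower, median -0.10, adjusted p = 1.2e-04) and antioxidant enzymes (15 of 21 lower, median -0.093, adjusted p = 0.0280) fell. Both lists had adjusted p = 0.673 with an estimated correlation. Single members included Ndufs4 (-0.41 ± 0.17), Atp5l (-0.38 ± 0.16), Cox7c (-0.37 ± 0.17) and Gpx1, a glutathione peroxidase (-0.31 ± 0.14). In edgeR 0 members of these lists passed when adjusted over the list alone. Control male 6, with the highest complex I and ribosomal levels of its group, was on the control side. When the 5 libraries were left out, the median was -0.11 for the cytosolic ribosome (adjusted p = 2.1e-10) and -0.084 for complex I (adjusted p = 2.0e-04). In that set the mitochondrial ribosome (-0.029), complex IV (-0.076), ATP synthase (-0.047), complexes II and III (-0.0045), proteasome (-0.00056) and antioxidant (0.00051) lists no longer passed.

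Glial and vascular lists also moved in males by camera. Astrocyte markers fell (16 of 20 lower, median -0.11, adjusted p = 0.00881), with Gfap, the astrocytic filament protein gene, at -0.33 ± 0.15. So did microglial (14 of 20, median -0.12, adjusted p = 0.0163) and tanycyte markers (16 of 19, median -0.12, adjusted p = 0.0165). These 3 again had adjusted p = 0.673 with an estimated correlation. Ependymal genes (17 of 18, median -0.29, adjusted p = 0.00325), meningeal fibroblast markers (15 of 19, median -0.29, adjusted p = 0.00489) and glucocorticoid-induced genes (11 of 15, median -0.27, adjusted p = 0.00881) fell likewise. The same held for inflammatory genes (16 of 22, median -0.10, adjusted p = 0.0380) and unfolded protein response genes (15 of 22, median -0.033, adjusted p = 0.0297). All 5 had adjusted p = 0.673 with an estimated correlation. Rises were called for presynaptic genes (20 of 21 higher, median 0.098, adjusted p = 0.00970), glutamatergic (19 of 21, median 0.083, adjusted p = 0.0163) and GABAergic synapse genes (15 of 17, median 0.087, adjusted p = 0.0281) and endothelial markers (12 of 18, median 0.10, adjusted p = 0.0297). These rises had adjusted p = 0.673 with an estimated correlation. Of these 12 lists, 4 were still past the threshold without the 5 libraries and the other 8 were not. The 4 were ependymal (-0.33, adjusted p = 3.7e-10), tanycyte (-0.12, adjusted p = 0.0114), presynaptic (0.085, adjusted p = 0.00230) and endothelial genes (0.11, adjusted p = 0.00552). In that set the smallest value was adjusted p = 0.803 with an estimated correlation.

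Of the other appetite genes in males, Agrp had a log2 fold change of -0.50 ± 0.49, Pomc -0.45 ± 0.45, Cartpt -0.13 ± 0.27, Hcrt -0.16 ± 0.57 and Pmch -0.17 ± 0.55. Lepr had 0.19 ± 0.18, Mc4r -0.17 ± 0.36 and Insr 0.086 ± 0.11. None of them passed. Control male 6 had 34.6 CPM of Agrp, the highest of its group, and without the 5 libraries Agrp had -0.091 ± 0.31. In that set Pomc had -0.24 ± 0.35, Cartpt -0.035 ± 0.14, Hcrt -0.021 ± 0.40, Pmch 0.098 ± 0.19, Lepr 0.27 ± 0.17, Mc4r -0.16 ± 0.22 and Insr 0.015 ± 0.082. In males edgeR called 0 of 18743 genes (smallest adjusted p = 0.940), with 647 at an unadjusted p under 0.05. With limma voom 0 were called and with DESeq2 1. That gene was Xist, read in the library labelled control male 7 and nearly absent from the other males. Beside Xist, the smallest p belonged to Gimap9 (2.74 ± 0.68) and Pycr1, an enzyme of proline synthesis (ENSMUSG00000025140, chromosome 11, 120635712 to 120643769). Pycr1 stood at 1.28 ± 0.356 CPM in 8 control and 2.35 ± 0.716 CPM in 8 obesogenic males, a log2 fold change of 0.88 ± 0.22. Next were Lgals3, encoding galectin 3 (-0.99 ± 0.28), and Cxcl12, encoding a chemokine (33.7 ± 4.79 and 45.2 ± 6.84 CPM, 0.43 ± 0.13). Each had an edgeR adjusted p = 0.940. Pycr1 was above the control mean in 8 of 8 obesogenic males and Cxcl12 in 8 of 8. In the set without the 5 libraries edgeR called 0 genes, with 504 at an unadjusted p under 0.05.

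**Figure D4:**
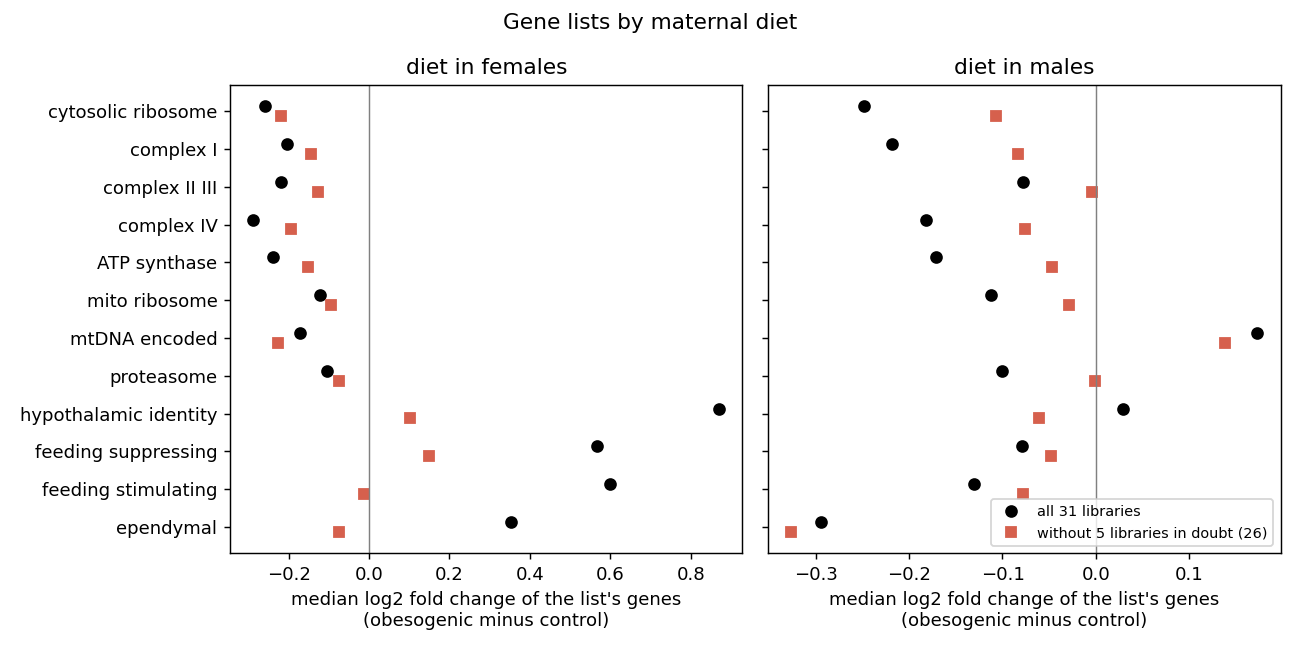
Each mark is the median log2 fold change, obesogenic minus control, of 1 gene list, in females (left) and males (right, on its own scale); black circles use all 31 libraries and red squares leave out the 5 libraries in doubt. The cytosolic ribosome lies at -0.26 and -0.22 in females and at -0.25 and -0.11 in males, and hypothalamic identity genes in females move from 0.87 to 0.10.

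Averaged over the sexes, which pools 15 obesogenic and 16 control libraries, the fall of translation and respiration genes had its smallest p-values. 76 of 77 cytosolic ribosomal protein genes were lower (median log2 fold change -0.25, camera adjusted p = 9.3e-28; adjusted p = 0.894 with an estimated correlation). In edgeR 63 of them passed when adjusted over the list alone. Of complex I, 35 of 36 were lower (median -0.21, adjusted p = 8.0e-14; adjusted p = 0.894 with an estimated correlation), 21 of them past the threshold over the list alone. All 13 cytochrome c oxidase genes (median -0.25, adjusted p = 9.7e-09, 11 adjusted over the list alone) and all 16 ATP synthase genes (median -0.20, adjusted p = 3.0e-08, 9 adjusted over the list alone) were lower. Both had adjusted p = 0.894 with an estimated correlation. Among the members of smallest p were Rpl13 (-0.35 ± 0.12) of the ribosome and Ndufb9 (-0.35 ± 0.11) and Ndufc2 (-0.27 ± 0.092) of complex I. For the other 2 lists they were Cox8a (-0.27 ± 0.093) and Cox5b (-0.33 ± 0.12) of cytochrome c oxidase, and Atp5l (-0.35 ± 0.12) and Atp5g2 (-0.20 ± 0.071) of ATP synthase.

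Mitochondrial ribosome genes (75 of 76 lower, median -0.12, adjusted p = 2.2e-13) and complexes II and III (11 of 13, median -0.14, adjusted p = 9.0e-05) also fell. Both lists had adjusted p = 0.894 with an estimated correlation and 0 members adjusted over the list alone. Mrpl54 had -0.29 ± 0.096 and Uqcr11 -0.36 ± 0.13. Proteasome (29 of 31 lower, median -0.10, adjusted p = 2.4e-06), antioxidant (17 of 21, median -0.095, adjusted p = 0.0122) and microglial genes (19 of 20, median -0.13, adjusted p = 9.1e-04) fell. These 3 lists had adjusted p = 0.894 with an estimated correlation. Meningeal fibroblast markers fell by a median of 0.34 (16 of 19 lower, adjusted p = 2.1e-04; adjusted p = 0.894 with an estimated correlation). Of them 2 passed over the list alone, Igfbp2 (-1.21 ± 0.34) with the smallest p. Hypothalamic identity genes rose (20 of 22 higher, median 0.42, adjusted p = 0.00448; adjusted p = 0.936 with an estimated correlation). Their median was 0.025 without the 5 libraries (adjusted p = 0.937). In that set proteasome (-0.047, adjusted p = 6.2e-04) and fibroblast genes (-0.16, adjusted p = 0.0344) still passed, and antioxidant (-0.048, adjusted p = 0.0529) and microglial genes (-0.075, adjusted p = 0.0645) did not. The sizes depended on control female 5, control male 6 and obesogenic female 3. Without these 3 the medians were -0.15 for the cytosolic ribosome, -0.097 for complex I, -0.12 for complex IV, -0.090 for ATP synthase, -0.058 for complexes II and III and -0.051 for the mitochondrial ribosome. All 6 were still past the threshold. With 2 surrogate variables in the model only the cytosolic ribosome of these 6 lists still passed (median -0.076, adjusted p = 5.5e-11). Corrected for gene length and GC content, and without the 5 libraries, 5 of the 6 passed, complexes II and III not, with medians from -0.12 for the cytosolic ribosome to -0.031 for the mitochondrial ribosome.

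The slope of a library's log2 CPM on log2 gene length, relative to the mean of the 26 libraries not in doubt, differed with maternal diet. It averaged -0.0079 ± 0.044 in 8 control and 0.049 ± 0.075 in 7 obesogenic females, and -0.033 ± 0.077 and 0.011 ± 0.040 in 8 and 8 males. The difference averaged over the sexes was 0.050 (permutation p = 0.022), and 0.035 without the 5 libraries (p = 0.020). By first title number all obesogenic libraries preceded the controls, so this test cannot separate diet from that order. Control male 6 had the lowest slope (-0.194) and obesogenic female 3 the highest (0.206), the libraries with the highest and lowest complex I levels of their groups. Across genes, the diet effect had a Spearman correlation with gene length of 0.276 in females and 0.293 in males. Longer genes thus tended to be higher in obesogenic offspring.

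For the averaged effect edgeR called 0 of 18743 genes (smallest adjusted p = 0.464), 1918 having an unadjusted p under 0.05. With limma voom 0 were called. DESeq2 called 5, namely Uty, Eif2s3y, Kdm5d, Ddx3y and Xist. On these genes the libraries labelled control female 7 and control male 7 went against their labels. By p, after Xist, the leading genes were Gimap9 (1.88 ± 0.47), Adamts1, a secreted protease (ENSMUSG00000022893, chromosome 16, 85793827 to 85803113; 0.36 ± 0.093), Ttc21b, a cilium transport gene (0.27 ± 0.072), and B3galt4, a glycosyltransferase gene (-0.46 ± 0.12). Each had an edgeR adjusted p = 0.464. Adamts1 averaged 8.60 ± 1.59 and 11.7 ± 1.70 CPM in control and obesogenic females (n = 8 and 7). In males it averaged 8.68 ± 1.37 and 10.5 ± 1.88 CPM (n = 8 and 8). It was above the control mean in 7 of 7 obesogenic females and 6 of 8 obesogenic males. Leaving the 5 libraries out, edgeR called 0 genes, with 1486 at an unadjusted p under 0.05. Camera called 15 lists, 0 with an estimated correlation (smallest adjusted p = 0.617).

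Whether maternal diet acted differently in daughters and sons was tested as an interaction, the female effect minus the male effect. Protein genes of the mitochondrial genome had the opposite sign in the sexes, and the difference passed by camera (12 of 13 lower, median difference -0.35, adjusted p = 2.5e-04; adjusted p = 0.843 with an estimated correlation). It was -0.095 and did not pass after correction for gene length and GC content (adjusted p = 0.0749). mt-Atp6 (ENSMUSG00000064357, mitochondrial genome, 7927 to 8607) is a subunit gene of ATP synthase. Its counts are uncertain because it overlaps mt-Atp8 and mitochondrial genes have near-identical nuclear copies. It averaged 32.1 ± 27.01 and 12.3 ± 3.64 CPM in control and obesogenic females (n = 8 and 7), and 13.2 ± 3.04 and 24.3 ± 20.4 CPM in males (n = 8 and 8). With an interaction of -2.26 ± 0.61 it was the 1 member that passed when adjusted over the list alone. Ependymal genes (17 of 18 higher in the female effect, median 0.59, adjusted p = 3.3e-06; adjusted p = 0.843 with an estimated correlation) and inflammatory genes (16 of 22, median 0.19, adjusted p = 0.00476; adjusted p = 0.777 with an estimated correlation) differed as well. Hypothalamic identity genes (21 of 22, median 0.91, adjusted p = 2.3e-04; adjusted p = 0.870 with an estimated correlation) differed too. That median was 0.11 without the 5 libraries (adjusted p = 0.101).

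Other neuropeptides (18 of 20 higher, median 0.51, adjusted p = 0.00168), feeding-suppressing genes (13 of 16, median 0.53, adjusted p = 0.0217) and heat shock genes (14 of 15, median 0.11, adjusted p = 0.0218) had a higher female than male effect. Each of the 3 had adjusted p = 0.870 with an estimated correlation. Astrocyte markers (18 of 20, median 0.12, adjusted p = 0.0158; adjusted p = 0.949 with an estimated correlation) and unfolded protein response genes (16 of 22, median 0.13, adjusted p = 5.1e-04; adjusted p = 0.843 with an estimated correlation) did so too. Members included Vgf, a neuropeptide precursor (0.47 ± 0.24), Pdia4, a protein disulphide isomerase (0.27 ± 0.092), and Lcn2, an acute phase protein gene (3.36 ± 1.44). The cytosolic ribosome did not differ past the threshold (median -0.0080, adjusted p = 0.982), nor did complex I (median -0.0074, adjusted p = 0.982). In the set without the 5 libraries both did, in the direction of a lower female effect (-0.10, adjusted p = 4.5e-04, and -0.071, adjusted p = 0.0149), each with adjusted p = 0.901 with an estimated correlation. The calls for mtDNA-encoded (-0.33, adjusted p = 3.6e-04), ependymal (0.23, adjusted p = 0.00237), unfolded protein response (0.071, adjusted p = 0.0239) and inflammatory genes (0.19, adjusted p = 0.00466) held in that set by camera. Those for other neuropeptides (0.016, adjusted p = 0.970), feeding-suppressing (0.22, adjusted p = 0.247), heat shock (0.086, adjusted p = 0.345) and astrocyte genes (0.014, adjusted p = 0.790) did not.

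For the interaction edgeR called 0 of 18743 genes, the smallest adjusted p being 0.9996, with 679 at an unadjusted p under 0.05. With limma voom 0 were called and with DESeq2 6, which were Uty, Kdm5d, Eif2s3y, Ddx3y, Xist and Slc17a7. Slc17a7, a vesicular glutamate transporter gene (ENSMUSG00000070570, chromosome 7, 45163949 to 45176142), averaged 94.6 ± 248.3 CPM in control females, where control female 5 had 721 CPM of its total, and 1.31 ± 1.48 CPM in obesogenic females. Pycr1 (-1.22 ± 0.31), Lgals3 (1.51 ± 0.40), mt-Atp6 and Xist completed the 5 smallest p-values by edgeR. Npy's diet effects of -0.75 ± 0.31 in females and -0.54 ± 0.29 in males were not shown to differ (interaction -0.20 ± 0.42, which did not pass). Across genes, female and male diet effects had a Pearson correlation of 0.0897 (0.0472 without the 5 libraries) and a Spearman correlation of 0.190 (0.135), with the same sign for 60.1% of genes (56.9%). Genes are not independent replicates. Once the 5 libraries were left out, edgeR again called 0 genes, with 651 at an unadjusted p under 0.05.

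Sex was compared within each maternal diet, females minus males. In control offspring, a list of Xist and 6 X-linked genes that escape X inactivation rose in females (7 of 7 higher, median log2 fold change 0.53, camera adjusted p = 4.8e-13). This call held, with adjusted p = 0.0167 with an estimated correlation. Without Xist, a test chosen after the data were seen, the 6 escape genes were higher (6 of 6, median 0.52, adjusted p = 7.4e-09) but missed the threshold with adjusted p = 0.0539 with an estimated correlation. They passed it without the 5 libraries (adjusted p = 7.2e-05 with an estimated correlation). Of the whole list 5 of 7 passed in edgeR over the list alone. Eif2s3x, a translation initiation factor gene, had 0.52 ± 0.15 and Ddx3x, an RNA helicase gene, 0.46 ± 0.14. No gene passed over all genes, Y-linked ones included, while control female 7 carried them and control male 7 did not. Adam12, a metalloprotease gene (ENSMUSG00000054555, chromosome 7, 133883199 to 134232146), had the smallest p. It stood at 4.75 ± 1.29 CPM in 8 control females and 2.44 ± 0.759 CPM in 8 control males. The log2 fold change was 0.96 ± 0.20 (edgeR adjusted p = 0.356), higher than the male mean in 8 of 8 female libraries.

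Of the other lists, hypothalamic identity (21 of 22 lower in females, median -0.86, adjusted p = 8.0e-06), feeding-stimulating (8 of 9, median -0.93, adjusted p = 0.00396), feeding-suppressing (12 of 16, median -0.49, adjusted p = 0.00117) and ependymal genes (17 of 18, median -0.48, adjusted p = 1.2e-05) were lower in control females, the group that held control female 5. These 4 lists had adjusted p = 0.731 with an estimated correlation. Their medians were -0.089, 0.018, -0.13 and -0.10 without the 5 libraries, and 0 of the 4 passed. Cytosolic ribosome (76 of 77 lower, median -0.15, adjusted p = 7.4e-09; adjusted p = 0.731 with an estimated correlation) and complex I (34 of 36, median -0.11, adjusted p = 0.00111; adjusted p = 0.810 with an estimated correlation) genes were lower in females, against males that included control male 6. So were mitochondrial ribosome (61 of 76, median -0.057, adjusted p = 0.00516; adjusted p = 0.848 with an estimated correlation) and proteasome genes (28 of 31, median -0.087, adjusted p = 5.6e-04; adjusted p = 0.731 with an estimated correlation). Their medians turned without the 5 libraries to 0.036, 0.023, 0.054 and 0.0058, the mitochondrial ribosome then being higher in females (adjusted p = 4.3e-04; adjusted p = 0.911 with an estimated correlation).

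Other neuropeptides (16 of 20 lower, median -0.35, adjusted p = 0.00128), astrocyte markers (19 of 20, median -0.12, adjusted p = 0.00771) and lipid synthesis genes (22 of 29, median -0.064, adjusted p = 0.00927) were lower in control females. These 3 lists also had adjusted p = 0.731 with an estimated correlation. Immediate early genes (19 of 20 higher, median 0.20, adjusted p = 0.00128), glutamatergic synapse genes (20 of 21, median 0.14, adjusted p = 0.00393) and meningeal fibroblast markers (18 of 19, median 0.23, adjusted p = 0.00709) were higher. So were mtDNA-encoded genes (10 of 13, median 0.21, adjusted p = 0.0127) and leptin and insulin signalling genes (18 of 21, median 0.069, adjusted p = 0.0468). All 5 lists had adjusted p = 0.731 with an estimated correlation. Of these 8, mtDNA-encoded (0.21, adjusted p = 1.7e-04) and fibroblast genes (0.40, adjusted p = 1.6e-04) were still called without the 5 libraries, with adjusted p = 0.911 with an estimated correlation. Over all genes edgeR called 0 of 18743 (smallest adjusted p = 0.356), with 823 at an unadjusted p under 0.05. With limma voom 0 were called, and DESeq2 called Adam12 alone. Among the smallest p-values after Adam12 were those of Slc17a7 (6.95), Cdhr1 (4.73 ± 1.04) and Doc2g (4.99 ± 1.11). Cdhr1 had 0.20 ± 0.20 and Doc2g -0.032 ± 0.35 without the 5 libraries.

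Without the 5 libraries edgeR called 11 genes between control females and males, 4 higher and 7 lower in females, with 453 at an unadjusted p under 0.05. The 2 libraries against their sex label were left out because of Xist and the Y-linked genes, so calls on those very genes are no independent evidence. Ddx3y averaged 73.3 ± 14.95 CPM in 6 males and had 0 reads in 6 females, in which it was at least 4568-fold lower against a floor of 3 counts over the group. Likewise Kdm5d (24.9 ± 2.25 CPM) was at least 1552-fold lower. Uty, Eif2s3y, Uba1y and the predicted gene Gm29650 were the other Y-linked calls, and Xist, Eif2s3x (0.61 ± 0.11), Ddx3x (0.53 ± 0.11) and 5530601H04Rik the X-linked ones. The 1 autosomal gene was Lamp5, encoding a lysosomal membrane protein of neurons (ENSMUSG00000027270, chromosome 2, 136052239 to 136069917). It was lower in females by a log2 fold change of -0.81 ± 0.12 (adjusted p = 1.1e-04), below the male mean in 6 of 6 female libraries. With all 31 libraries Lamp5 had 0.16 ± 0.32, and without only the 3 libraries that stood apart -0.59.

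In obesogenic offspring, where no library went against its sex label, the list of Xist and escape genes again rose in females (7 of 7 higher, median 0.52, camera adjusted p = 2.3e-21). This held, with adjusted p = 7.9e-04 with an estimated correlation, and 7 of 7 passed when adjusted over the list alone. Without Xist the 6 escape genes still passed (median 0.51, adjusted p = 7.4e-15; adjusted p = 0.00273 with an estimated correlation). Kdm5c, an X-linked histone demethylase gene, had 0.60 ± 0.12 and Kdm6a, another, 0.76 ± 0.19. Kdm5c was above the male mean in 7 of 7 female libraries. Inflammatory genes were higher in obesogenic females (17 of 22, median 0.17, adjusted p = 1.4e-04; adjusted p = 0.0684 with an estimated correlation), with Socs3, a feedback inhibitor of cytokine and leptin signalling, at 0.56 ± 0.19. Lipid synthesis genes were lower (25 of 29, median -0.11, adjusted p = 7.2e-05; adjusted p = 0.598 with an estimated correlation), with Nsdhl, an X-linked enzyme of cholesterol synthesis, at -0.34 ± 0.11. Both lists kept their calls without the 5 libraries by camera (medians 0.25 and -0.12), with adjusted p = 0.0525 and adjusted p = 0.157 with an estimated correlation.

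Lower in obesogenic females were genes of the cytosolic ribosome (76 of 77, median -0.17, adjusted p = 8.6e-08), complex I (35 of 36, median -0.11, adjusted p = 0.00144) and complexes II and III (13 of 13, median -0.15, adjusted p = 0.00363). The same was found for complex IV (13 of 13, median -0.16, adjusted p = 0.00363) and ATP synthase (16 of 16, median -0.13, adjusted p = 0.00728). These 5 lists had adjusted p = 0.725 with an estimated correlation. Lower too were genes of the proteasome (29 of 31, median -0.099, adjusted p = 1.9e-04), mitochondrial genome (13 of 13, median -0.19, adjusted p = 0.00856), citric acid cycle (15 of 20, median -0.062, adjusted p = 0.0404) and oligodendrocytes (18 of 20, median -0.13, adjusted p = 0.0126). These 4 too had adjusted p = 0.725 with an estimated correlation. The mitochondrial ribosome was lower too (66 of 76, median -0.072, adjusted p = 0.00892; adjusted p = 0.806 with an estimated correlation). Higher were immediate early (16 of 20, median 0.26, adjusted p = 0.00126), unfolded protein response (17 of 22, median 0.10, adjusted p = 0.00196) and heat shock genes (10 of 15, median 0.058, adjusted p = 0.0387). So were ependymal (15 of 18, median 0.20, adjusted p = 0.0387), meningeal fibroblast (14 of 19, median 0.24, adjusted p = 0.0404) and glucocorticoid-induced genes (11 of 15, median 0.18, adjusted p = 0.0404). All 6 had adjusted p = 0.725 with an estimated correlation. Obesogenic female 3, the lowest of its group in complex I, was on the female side. In the set without the 5, complex I (median -0.045, adjusted p = 0.0671), the mitochondrial ribosome (-0.025, adjusted p = 0.310) and the mitochondrial genome (-0.12, adjusted p = 0.105) did not pass. Nor did citric acid cycle (-0.038, adjusted p = 0.105), oligodendrocyte (-0.078, adjusted p = 0.0577) and glucocorticoid lists (0.092, adjusted p = 0.477). Corrected for gene length and GC content, the mitochondrial genome's median turned to 0.042 (adjusted p = 0.627). The medians of the others moved by over 1.5 times in that set for the cytosolic ribosome (-0.068), complexes II and III (-0.061), complex IV (-0.075), ATP synthase (-0.059), heat shock (0.12) and ependymal genes (0.12). Whether sex differences differed between maternal diets was tested as the interaction.

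In this comparison edgeR called 0 of 18743 genes (smallest adjusted p = 0.0702), 681 having an unadjusted p under 0.05, with 1 dispersion per gene shared by all 4 groups. DESeq2 called 12 genes, limma voom 3 (Kdm5c, Uba1y and Kdm6a), and edgeR on the 2 obesogenic groups alone 12. Besides sex-linked genes, the smallest p belonged to Rbm34, an RNA-binding protein gene (ENSMUSG00000033931, chromosome 8, 126947172 to 126971071). It stood at 19.1 ± 2.18 CPM in 7 females and 25.1 ± 2.19 CPM in 8 males (-0.39 ± 0.087, adjusted p = 0.168) and was below the male mean in 7 of 7 female libraries. Next were C4b (0.50 ± 0.13), a complement gene whose counts are uncertain because of its near-identical copy C4a, Tfrc (-0.39 ± 0.10), Aqp5 (3.52 ± 0.91) and Dok3 (0.67 ± 0.18). Without the 5 libraries edgeR called 14 genes, 5 higher and 9 lower in females, with 1024 at an unadjusted p under 0.05. Ddx3y averaged 77.8 ± 9.10 CPM in 8 males and had 0 reads in 6 females, at least 4723-fold lower, and the X-linked calls were Xist, Kdm5c, Kdm6a, Eif2s3x, Pbdc1 and Nxf3. The 2 autosomal calls were Tfrc, encoding the transferrin receptor (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794; -0.44 ± 0.090, adjusted p = 0.0435) and Lamp5 (-0.52 ± 0.11, adjusted p = 0.0476). Both were below the male mean in 6 of 6 female libraries. With gene length and GC content corrected as well, Lamp5 no longer passed in obesogenic offspring (-0.53, adjusted p = 0.0594) and still did in control offspring (-0.83, adjusted p = 1.5e-04). With all 31 libraries its value in obesogenic offspring was -0.38 ± 0.33.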

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

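The tests of explanations given here were chosen only after the results were seen, except the splits of the libraries for the 2 sex comparisons without the 5 libraries in doubt, which were fixed before for the count of all genes.

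Translation and respiration genes were lower in offspring of obesogenic dams, averaged over the sexes. Gene length and GC bias and the 5 libraries in doubt stay open as causes, because the lists stayed lower past the threshold after correction (6 of 6) and without these libraries (6 of 6) only with the preset correlation, and 0 of 6 with an estimated one. Complex I shrank from -0.208 to -0.124 and to -0.112, and complex IV from -0.245 to -0.150 and to -0.139, by these 2 changes singly. After both changes together 5 of the 6 passed with smaller medians (complex I from -0.208 to -0.048, ATP synthase from -0.204 to -0.058, complex IV from -0.245 to -0.052, the mitochondrial ribosome from -0.119 to -0.031, the cytosolic ribosome from -0.254 to -0.118), and complexes II and III did not (from -0.143 to -0.014), so both together could account for a part of the size that differs by list. Correlation between the genes of a list (0 of 6 passed with it estimated from all libraries), the maternal diet, and litter or batch, for which no labels were used here, stay open too, and chance could not be excluded, since 80 of 100 splits of the libraries, the real one included, called as many lists (11 by the real split, up to 30 by another).

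The library labelled control female 5 stood apart (median correlation 0.910). Low RNA quality or complexity is argued against by its 21775 genes with reads, inside the 21311 to 22918 of the 28 other libraries, and a mixture with a large share of hypothalamus by its Pmch, Hcrt, Avp and Oxt at 0.00308, 0.100, 0.0692 and 0.0976 percent of the median of the others. Tissue from outside the hypothalamus remains a candidate explanation, since 20 of 22 hypothalamic identity genes were lowest in it of all libraries. Of the 15 olfactory bulb genes 14 were highest in it, among them Cdhr1 at 754 CPM, Slc17a7 at 721 and Omp at 202.3, so olfactory bulb may be its source; these genes had been seen high in it before the list was written. No biological explanation was tested, because no label sets this library apart.

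2 control libraries had sex-linked genes that went against the label. RNA of both sexes mixed is argued against by Xist in the library labelled control female 7 at 0.0771 percent of the median of the other females. An exchange between the 2 groups would put 1 library out of place in each, and 2 were, 1 labelled control female and 1 labelled control male; whether they were exchanged with each other or each mislabelled singly cannot be told apart, since nothing else identifies an animal. Without these 2 libraries alone, the sex comparison in control offspring called 10 genes where all libraries gave 0, and such an exchange could account for that difference.

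In 71 tests for a library far from the rest of its group, 15 found one. The measures overlapped and included median correlation, Xist and Y-linked genes, by which the libraries in doubt had been picked. The number to be found by chance is therefore not known. Control male 6 had 34.6 CPM of Agrp and 2124 CPM of Pmch, both the highest of its group, 18734 genes with reads, the fewest, a median correlation of 0.914, and the highest mean log2 CPM of complex I (7.66) and cytosolic ribosome genes (8.99). Obesogenic female 3 had 18513 genes with reads, a median correlation of 0.936 and the lowest mean log2 CPM of complex I (5.92). Obesogenic female 6 had the highest Pomc of its group, 268.6 CPM. Control female 5 had 9.05 CPM of Cartpt and a mean log2 CPM of -1.87 for hypothalamic identity genes, the lowest of its group, besides its median correlation of 0.910. The library labelled control male 7 had 575 CPM of Xist, and the library labelled control female 7 had 139 CPM of Y-linked genes.

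9 gene lists had a diet effect that differed between the sexes by the interaction test. The median difference, female minus male effect, was -0.35 for mitochondrial genome genes, 0.53 for feeding-suppressing genes, 0.51 for other neuropeptides, 0.91 for hypothalamic identity, 0.13 for the unfolded protein response, 0.11 for heat shock, 0.19 for inflammation, 0.12 for astrocyte and 0.59 for ependymal genes. With an estimated correlation 0 of the 9 passed, and 90 of 100 splits called as many lists (9 by the real split, up to 28 by another), so chance could not be excluded.

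For single genes in all libraries, the real split called 0 in each comparison, so 100 of 100 splits were bound to call as many and the splits decide nothing about chance there. The highest count of another split was 2 for diet in females, 0 in males, 1 averaged, 0 for the interaction, 0 for sex in control and 1 in obesogenic offspring. For lists, chance could not be excluded for diet in females (15 called, 54 of 100 splits as many, up to 30), diet in males (21, 18 of 100, up to 27), sex in control offspring (17, 76 of 100, up to 29) or sex in obesogenic offspring (19, 7 of 100, up to 24). Some other splits called more lists than the real one. List calls in such numbers thus arose without the real groups, and their cause was not tested. The estimated correlation between the genes of a list, for instance 0.729 for complex I and 0.878 for the cytosolic ribosome, lay far above the preset 0.01. Without the 5 libraries in doubt 14 genes were called between the sexes in obesogenic offspring, 12 of them sex-linked. Another split called at most 3 (1 of 100 as large, the real one). The 2 control libraries left out because of Xist and Y-linked genes had shared 1 dispersion per gene with the obesogenic groups. Leaving out these 2 alone moved the obesogenic count from 0 to 9, so this count does not decide about chance. In control offspring 11 were called against at most 1 (1 of 100), but 2 control libraries had been left out because of Xist and Y-linked genes, which fixes that outcome, so it decides nothing. For autosomal genes alone 1 was called in control offspring (2 of 100 splits as many, at most 1 by another) and 2 in obesogenic offspring (2 of 100, at most 3 by another). So few splits called as many, but another split called as many or more, and the counts say nothing about chance for Lamp5 or Tfrc singly.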

How the results depend on the processing

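The settings without the 2 libraries against their sex label, without the 5 libraries in doubt and with the correction for gene length and GC content were tests chosen only after the data had been seen, and the others were planned. No paired analysis was possible because the labels carry no replicate, litter or animal number shared between groups, and the replicate numbers used here only follow the order of the samples. Of values of single named genes under another setting, 2743 kept their direction and side of the threshold, 108 passed only there and 50 changed sign. Of called gene lists, 317 values stayed past the threshold in the same direction, 369 kept the direction without passing and 50 turned. 84 of the counts of genes or lists stayed within 1.5 times and 40 did not. DESeq2-type size factors (RLE), no filter on low counts, the stricter filter and leaving out the 2 libraries with 2 numbers in the title moved 0 of the counts of genes they were tried on and turned 0 signs. The cause of the changes given here was not tested, except that fewer libraries and fewer genes enter some settings by construction.

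Against 0 genes by edgeR in each comparison, DESeq2 called 6 for diet in females, 1 in males, 5 averaged, 6 for the interaction, 1 for sex in control and 12 in obesogenic offspring. For sex in obesogenic offspring, limma voom called 3, the fit with 2 surrogate variables 6, the fit without the libraries that stand apart 1, and the 2 groups alone 12. Without the 2 libraries against their sex label 10 genes were called for sex in control and 9 in obesogenic offspring, without the 5 libraries 11 and 14, and without them and corrected for length and GC content 13 and 14. The biological coefficient of variation was 0.297 with all libraries and 0.197 without the 5.

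For gene lists, camera with the preset correlation called 15 for diet in females (5 higher and 10 lower), 21 in males (5 and 16), 11 averaged (1 and 10), 9 for the interaction (8 and 1), 17 for sex in control (6 and 11) and 19 in obesogenic offspring (8 and 11). With an estimated correlation, and with fry, the counts in that order were 0, 0, 0, 0, 1 and 1 by either test. With 2 surrogate variables 8 lists were called for diet in females (5 and 3) and 3 for sex in control offspring (3 and 0). The balance of directions turned there for the averaged diet effect (6 and 3) and diet in males (9 and 7), and for the interaction it was 4 and 5. Without the libraries that stand apart the count was 17 for the averaged diet effect (7 and 10) and 17 for the interaction (6 and 11). The 12 lists called there for sex in control offspring were all higher, and the 14 for diet in males divided into 8 and 6. The set without the 5 libraries gave 7 for diet in males (3 and 4), 16 for the interaction (3 and 13) and 5 for sex in control offspring (5 and 0). It gave 13 for diet in females (3 and 10), 15 averaged (5 and 10) and 15 for sex in obesogenic offspring (8 and 7). With the length and GC correction added, the counts were 8 for diet in males (5 and 3), 16 for the interaction (3 and 13), 5 for sex in control (5 and 0) and 11 in obesogenic offspring (8 and 3). The correction alone called 9 for sex in obesogenic offspring, 6 higher and 3 lower against 8 and 11, and for the averaged diet effect 4 higher and 9 lower against 1 and 10.

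With DESeq2, the log2 fold change of 2 gene values changed sign, to Cck -0.059 and Lamp5 -0.52 for sex in control offspring.

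With limma voom and sample quality weights, the log2 fold change of 13 gene values changed sign, to Insr -0.0028 and Islr 0.068 for diet in females, Pomc 0.072, Cartpt 0.075, Hcrt 0.54, Pmch 0.23, Insr -0.027, Sod1 0.00035, Uqcrh 0.014 and Psmd4 0.0016 for diet in males, and Ndufa5 0.10, Rpl6 0.023 and Lamp5 -0.48 for sex in control offspring.

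With 2 surrogate variables, the log2 fold change of 11 gene values changed sign, to Lepr -0.076 and Insr -0.059 for diet in females, Cartpt 0.10, Hcrt 0.45, Pmch 0.33, Insr -0.017, Sod1 0.018 and Uqcrh 0.013 for diet in males, Pgr -0.026 for diet averaged over the sexes, and Cck -0.016 and Lamp5 -0.57 for sex in control offspring. The direction of 13 list results turned in this setting, with medians of complexes II and III 0.031, ATP synthase 0.013, the mitochondrial ribosome 0.0094, antioxidant enzymes 0.0081 and proteasome genes 0.017 for diet in males, the mitochondrial ribosome -0.0078, antioxidant enzymes -0.0086 and proteasome genes 0.0031 for diet averaged over the sexes, and the mitochondrial ribosome 0.0084, feeding-stimulating genes 0.086, leptin and insulin signalling -0.0065, other neuropeptides 0.048 and glutamatergic synapses -0.029 for sex in control offspring. The averaged medians of the mitochondrial ribosome and of antioxidant enzymes kept their sign while the direction of the test turned.

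Without the libraries that stand apart, the log2 fold change of 7 gene values changed sign, to Pmch -0.017 for diet in females, Hcrt 0.14, Pmch 0.14 and Insr -0.0079 for diet in males, and Ndufa5 0.061, Rpl6 0.012 and Lamp5 -0.59 for sex in control offspring. The direction of 12 list results turned in this setting, with medians of other neuropeptides -0.017 and ependymal genes -0.070 for diet in females, complexes II and III 0.0028 and proteasome genes 0.00083 for diet in males, and complex I 0.051, the mitochondrial ribosome 0.064, the cytosolic ribosome 0.051, feeding-stimulating genes 0.028, leptin and insulin signalling -0.039, other neuropeptides 0.028, proteasome genes 0.022 and glutamatergic synapses -0.027 for sex in control offspring.

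With all 5 libraries in doubt left out, the log2 fold change of 5 gene values changed sign, to Pmch 0.098 for diet in males, and Doc2g -0.032, Ndufa5 0.018, Rpl6 0.0043 and Lamp5 -0.81 for sex in control offspring. The direction of 10 list results turned in this setting, with medians of other neuropeptides -0.047 and ependymal genes -0.076 for diet in females, and complex I 0.023, the mitochondrial ribosome 0.054, the cytosolic ribosome 0.036, leptin and insulin signalling -0.0077, other neuropeptides 0.047, proteasome genes 0.0058, astrocyte genes 0.047 and glutamatergic synapses -0.035 for sex in control offspring.

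With the length and GC correction, the log2 fold change of 3 gene values changed sign, to Insr -0.078 for diet in females, Hcrt 0.029 for diet in males, and Pbdc1 -0.021 for sex in control offspring. The direction of 2 list results turned in this setting, with medians of the mitochondrial genome 0.093 for diet in females, and the mitochondrial genome 0.042 for sex in obesogenic offspring.

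With that correction and without the 5 libraries, the log2 fold change of 9 gene values changed sign, to Doc2g 0.042 and Insr -0.11 for diet in females, Cartpt 0.050, Hcrt 0.12, Pmch 0.15 and Insr -0.014 for diet in males, and Doc2g -0.046, Ndufa5 0.023 and Lamp5 -0.83 for sex in control offspring. The direction of 13 list results turned in this setting, with medians of ependymal genes -0.077 for diet in females, complexes II and III 0.034, antioxidant enzymes 0.015 and proteasome genes 0.015 for diet in males, complex I 0.022, the mitochondrial ribosome 0.060, the cytosolic ribosome 0.029, leptin and insulin signalling 0.0011, other neuropeptides 0.046, proteasome genes 0.00028, astrocyte genes 0.033 and glutamatergic synapses -0.014 for sex in control offspring, and the mitochondrial genome 0.044 for sex in obesogenic offspring. Leptin and insulin signalling kept the sign of its median while the direction of the test turned.

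The depth of 23118626 to 38547288 read pairs per library left 18743 of 54532 genes above the filter on low counts. With no filter 32058 genes were tested and edgeR called 0 in each comparison, with 2267 to 4054 at an unadjusted p under 0.05. Of the genes above the filter, 1.5-fold changes were recovered less often than 2-fold ones in the simulated comparison, so an absent call there does not exclude a change of that size.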

Other observations

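The comparisons of this part, the sets without the 5 libraries and the relation of Prl to Gh, were tests chosen only after the data had been seen.

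Without the 5 libraries in doubt, camera called lists that it had not called with all 31. Averaged over the sexes, glucocorticoid-induced genes were lower in offspring of obesogenic dams (13 of 15 lower, median log2 fold change -0.23, adjusted p = 0.00202; adjusted p = 0.617 with an estimated correlation). Tsc22d3, a classical glucocorticoid target, had -0.24 ± 0.11 and the metallothionein gene Mt2 -0.26 ± 0.13. Immediate early genes of neuronal activity were higher (18 of 20 higher, median 0.17, adjusted p = 4.3e-04; adjusted p = 0.617 with an estimated correlation), with Arc at 0.38 ± 0.13 and Fos at 1.07 ± 0.41. Leptin and insulin signalling genes (19 of 21 higher, median 0.064, adjusted p = 0.00730), with Stat3, the transcription factor below the leptin receptor, at 0.17 ± 0.054, were higher too, with adjusted p = 0.617 with an estimated correlation. Ependymal genes were lower (17 of 18 lower, median -0.17, adjusted p = 8.4e-05; adjusted p = 0.617 with an estimated correlation). In none of these lists did a single member pass in edgeR over all genes, and the members named here were chosen after their values were seen.

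In the same 26 libraries, midbrain monoamine markers had a lower female than male diet effect (9 of 9 lower, median difference -0.60, adjusted p = 5.2e-04; adjusted p = 0.667 with an estimated correlation). They were higher in control females than in control males (median 0.46, adjusted p = 0.00104; adjusted p = 0.911 with an estimated correlation). Slc6a3, the dopamine transporter gene, had an interaction of -2.51 ± 1.02, and Th, the dopamine synthesis gene, a sex difference of 0.49 ± 0.20 in control offspring. Interferon response genes were higher in obesogenic females than in obesogenic males (17 of 23 higher, median 0.19, adjusted p = 5.4e-04; adjusted p = 0.745 with an estimated correlation), with Isg15 at 0.72 ± 0.25 and Gbp2 at 0.64 ± 0.22.

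With all 31 libraries, 17 of the 49 lists were called by camera in 0 of the 6 comparisons. Their smallest adjusted p-values over the comparisons were 0.0528 for nutrient sensing, 0.0541 for blood, 0.0899 for choroid plexus, 0.0907 for interferon response, 0.102 for midbrain, 0.118 for fatty acid oxidation, 0.164 for mitochondrial biogenesis, 0.208 for sex steroid and 0.230 for thalamic genes. They were 0.349 for oligodendrocyte precursors, 0.392 for glycolysis, 0.394 for clock, 0.449 for pituitary, 0.608 for perineuronal matrix, 0.654 for thyroid, 0.828 for telencephalic and 0.892 for mural genes. A p that missed the threshold does not show that a list did not differ.

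Prl and Gh, which encode the pituitary hormones prolactin and growth hormone, ranged from 0 to 4635 and from 0 to 1477 CPM between libraries, the highest of both in control female 4. A candidate explanation is pituitary tissue carried over at dissection: log2 Prl and log2 Gh correlated over 31 libraries (Pearson r = 0.882, permutation p = 1e-05; Spearman rho = 0.806, p = 1e-05, the smallest that 100000 permutations can give), and r was 0.869 without the 2 libraries farthest on Prl. Within groups Pearson's r was 0.965 in control females (exact permutation p = 0.0021), 0.852 in control males (p = 0.012), 0.985 in obesogenic females (p = 0.0012) and 0.939 in obesogenic males (p = 0.051, with rho = 0.452, p = 0.27), so the relation did not hold by the test in the last group. Over the 7 relations computed, the adjusted p was 2.3e-05 for all libraries and 0.051 at most. The pituitary list was called in 0 of the 6 comparisons.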
